A study of Rattus norvegicus with 16 samples.

How the data were processed

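Gene expression was measured in the hippocampus of 16 male Wistar rats with 16 Agilent 1-colour arrays, one array for each rat. Per the labels and the series text, a solution of 1 µl was infused into the right amygdala of rats that had undergone surgery at 5 weeks of age. The control rats received saline at pH 2.2, and the Fe rats received 100 mM ferric chloride in saline at the same pH. The groups held 4 arrays each and were named control, Fe day 5, Fe day 15 and Fe day 30 after the interval between infusion and tissue collection. The controls were collected on day 15 alone, so that Fe day 5 and Fe day 30 differed from them in age and in time since infusion as well as in iron.

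Per the submitters' processing notes, the scanned images were read with Agilent Feature Extraction 9.5. The deposited scanner files gave, per the file headers, a processed signal for each spot, which is a background-subtracted and spatially detrended intensity on a linear scale. No scaling between arrays was found in these files. The deposited series table of intensity values equalled the processed signal of the matching scanner file in 100% of its entries at a relative tolerance of 1e-06, so it was not run as a separate alternative. The column medians of that table were 89.4, 65.1, 96.8 and 66.2 for control replicates 1 to 4, 93.1, 108, 84.3 and 100 for Fe day 5, 100, 89.1, 70.6 and 75.8 for Fe day 15, and 79.7, 81.9, 87.4 and 93.5 for Fe day 30. The files also gave the median pixel intensity of each spot and of its local background per the file headers, which entered only an alternative background correction. The marks for spots above background, saturated spots and non-uniform spots were taken from the deposited files as they stood.

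Each array held 45018 spots, of which 1639 were control spots and 43379 were probes for transcripts. The processed signal was placed on a log2 scale, and the 75th percentile of each array was subtracted. Spots marked as non-uniform or as population outliers were left out, and the remaining spots of a probe were averaged, which gave 41012 distinct probes, 263 of them printed in 10 spots. A further 122 probes with a single spot were left out because that spot carried such a mark. Probes were kept where they were well above background on all arrays of at least 1 group, which left 30548 probes. No spot was saturated. Probes were given gene symbols through their RefSeq accession and a RefSeq gene table on the assembly GRCr8, used for names alone, which matched 15080 of the 16116 probes with a RefSeq mRNA accession. For the 3312 genes with several probes the probe with the highest mean over the 16 arrays was used. This gave 26565 features, called genes here, of which 9588 (36.1%) had a symbol and 16977 were probes without one.

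Group means were fitted with limma 3.58.1 in R 4.3.3 in a one-way model of all 16 arrays, with 12 residual degrees of freedom. The 3 Fe groups were each compared with the controls, and the Fe days with one another, which made 6 comparisons, and a moderated F-test covered the 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and all tests were two-sided. The p-values measure the spread between these animals. The number of arrays limits the precision. The median residual SD was 0.19 on the log2 scale, the median standard error of a difference between groups was 0.13, and a gene at that spread needed a log2 difference of 0.29 for an unadjusted p of 0.05.

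Gene groups were tested with camera from limma at a preset correlation of 0.01 between genes, on 39 lists with at least 5 measured members each, adjusted over the lists. The lists covered 6 areas of lipid metabolism (cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid transport, eicosanoids with phospholipases, and sphingolipids with myelin lipids), responses to injury, markers of the cell types and regions a hippocampal dissection could hold, genes of neuronal excitability, and general cell biology. The 6 lipid lists together held 157 measured genes and were also tested as 1 list. Beside each call the adjusted p of camera with the correlation estimated from the data is given. Fry from limma, which tests whether the genes of a list move one way on balance without comparing them with other genes, was run as well. The score of a list on an array is the median, over the members, of the log2 signal minus the control mean of that member. Scores of 2 groups of 4 arrays were compared by exact permutation, for which 0.0286 is the smallest p that can be reached, and intervals of 95% for the lipid scores came from a linear model of the 16 scores.

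Genes to be named were chosen by a rule. For each Fe day against control these were the 8 largest rises and 8 largest falls among called genes with a symbol whose 4 Fe values all lay on one side of the 4 control values, and where fewer than 3 passed in a direction, the genes of lowest unadjusted p up to 3, given as not past the threshold. To these were added up to 3 members of lowest p from each list that passed, from at most 8 lists per comparison, and from every lipid list. A fixed set of 14 genes was to be named whatever the result, among them Gfap, Vim, Aif1, Cd68, Hmox1, Ptgs2, Npy, Bdnf, Fos, Arc, Apoe, Apod and Ttr. Some genes that the rule selects are not reported here. Between Fe days, 3 genes in each direction were taken in the same way. The groups, the comparisons, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

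The arrays lay on 7 slides. Slides 1 to 4 each held 1 control array, and 6 Fe arrays shared a slide with a control. All control arrays and Fe day 5 replicates 1 to 3 were in position 1 of their slide, and Fe day 5 replicate 4 and all arrays of Fe day 15 were in position 2. Fe day 30 replicates 1 and 2 were in position 2 and replicates 3 and 4 in position 4. The alternatives tried were other scalings, another background correction, other filters, every probe on its own, a fit of the compared groups alone, blocks for slide and for replicate number, array weights, other settings of the spread, other thresholds, other list tests and leaving out each array. The background correction by normexp was planned on the mean pixel intensity, which the files did not hold, so the median was used. A block for scan date was not run, because the headers gave 1 date for all arrays. Alternatives chosen after seeing the data were leaving out arrays high in markers of other tissues, a block for array position, keeping the marked spots, pooling the 12 Fe arrays, and permuting list scores.

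The procedure was tested on simulated data for Fe day 15 against control, with 26565 genes and 50 genes changed at each of 4 sizes. It recovered 36% of genes changed by 0.5 on the log2 scale, 78% at 1, 86% at 2 and 98% at 3. The genes of mitochondrial respiration were also shifted, by 0.3 on the log2 scale. Of the 171 genes called there 6.43% were unchanged, and an unchanged comparison gave 0 calls. The simulated noise was independent between probes and had the same spread on every array. The real arrays differed in spread, so these shares need not hold for them.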

Results

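RNA levels were measured in the hippocampus of 16 rats, 4 per group, after an infusion into the right amygdala of saline (control) or of 100 mM ferric chloride, an iron salt that sets off recurrent limbic seizures and serves as a model of epilepsy after head injury. The Fe groups were sampled 5, 15 and 30 days after the infusion, which the series text calls the acute, sub-chronic and chronic phases, and the controls at day 15. The 75th percentile of the processed signal ran from 553 in control replicate 4 to 924 in Fe day 5 replicate 4. Between 32189 and 35406 spots per array, 74.2% to 81.6% of the transcript probes, were well above background. Across genes, control arrays correlated with one another at 0.993 to 0.995 (Pearson's r of log2 signals), against 0.980 to 0.990 within Fe day 5, 0.982 to 0.992 within Fe day 15 and 0.977 to 0.993 within Fe day 30. The median SD of a gene within a group was 0.13 on the log2 scale in the controls and 0.18, 0.18 and 0.19 in the Fe groups at days 5, 15 and 30.

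The comparison of Fe day 5 with control asks which genes differed in the acute phase. Markers of the meninges and of fibroblasts, the cells of the brain's coverings and connective tissue, rose with a median log2 fold change of 1.65, and 18 of 19 measured members were higher. Lum, a proteoglycan of collagen fibrils, stood at 1.65 ± 0.69 (SE, n = 4 per group) and Slc22a6, an organic anion transporter, at 2.00 ± 0.86. Markers of the choroid plexus, the epithelium that makes cerebrospinal fluid, rose by a median of 1.06 with 17 of 17 members higher, among them Igfbp2 at 2.33 ± 1.2 and Igf2, which is also in the meninges list, at 1.84 ± 1.0. Immediate early genes, which neurons switch on within minutes of firing, fell by 0.28 in the median, with 19 of 26 members lower. Arc, a protein of the synapse, stood at −1.09 ± 0.43, Trib1 at −0.88 ± 0.28, Dusp6, a phosphatase that acts on ERK, at −0.81 ± 0.30 and Egr4 at −0.58 ± 0.21.

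Camera gave an adjusted p of 4.4e-07 for the meninges list, 5.8e-04 for choroid plexus and 0.0020 for immediate early genes. With an estimated correlation the adjusted p was 0.74 for each of the 3 lists. In these 3 lists 0 members were called over all genes and 0 adjusted over the list alone. A further 8 lists rose at day 5. Blood markers rose by a median of 0.79 (9 of 10 members higher, adjusted p = 1.0e-04) and markers of pericytes and smooth muscle, the cells around small vessels, by 0.33 (12 of 13, adjusted p = 1.6e-04), and for both the adjusted p was 0.67 with an estimated correlation. In the blood list 0 members were called over all genes and 2 were called adjusted over the list alone, namely S100a9, a protein of neutrophils, at 1.55 ± 0.34 (2.93-fold) and its partner S100a8 at 2.56 ± 0.58, which was above background on 1 of 4 control arrays. The other 6, all at an adjusted p of 0.74 or 0.75 with an estimated correlation, included genes of the extracellular matrix with a median of 0.55 (16 of 21 higher, adjusted p = 0.013) and complement with 0.36 (13 of 18, adjusted p = 0.020). Cytokines and chemokines had a median of 0.23 (20 of 24, adjusted p = 0.0095) and endothelial markers 0.17 (16 of 19, adjusted p = 0.027). Oligodendrocyte and myelin genes had 0.15 (19 of 21, adjusted p = 0.012) and eicosanoid and phospholipase genes 0.13 (18 of 26, adjusted p = 0.043). In these 6 lists 1 member, of the complement list, was called adjusted over the list alone. Among the cytokines Il1b stood at 1.12 ± 0.48 and Ccl5 at 1.18 ± 0.51, and among the matrix genes Ccn1 at 1.04 ± 0.38.

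**Figure D1:**
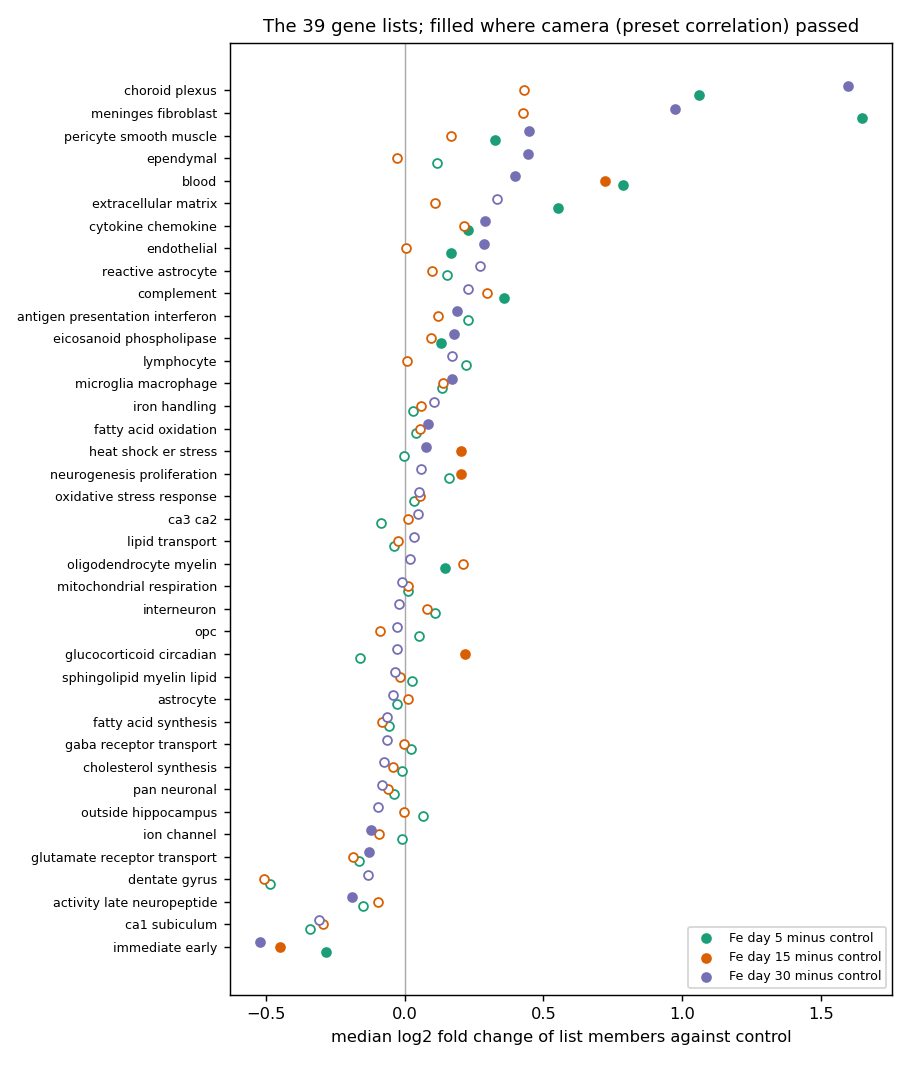
Median log2 fold change against control of the measured members of each of the 39 gene lists, with 1 point per list and Fe day (n = 4 arrays per group). Filled points passed camera with the preset correlation, and at day 30 the medians ran from −0.52 for immediate early genes to 1.60 for choroid plexus.

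Of 26565 genes limma called 0 at day 5, with 2746 at an unadjusted p under 0.05, 1079 of them higher and 1667 lower, and a lowest adjusted p of 0.44. Array weights and a fit of the 2 groups alone in limma also called 0. The genes of lowest p, none past the threshold, were Arhgap17, a GTPase-activating protein, at 1.14 ± 0.23 (2.20-fold higher), S100a9, and Cyb561a3 at 0.83 ± 0.19, all at an adjusted p of 0.47. Downward they were Tmem202 at −0.36 ± 0.073, Slmap at −0.39 ± 0.087 and the transcription factor Stat6 at −0.73 ± 0.16, at the same adjusted p. The pericyte examples Mustn1 and Tagln stood at 0.93 ± 0.31 and 1.24 ± 0.48, and the myelin gene Mal at 0.47 ± 0.25. The scores of single arrays were uneven. Choroid plexus scores were 1.76 in replicate 2 and 2.21 in replicate 3, against a highest control score of 0.20, and meninges scores were 3.89 and 1.84 in the same arrays. Without these 2 arrays and Fe day 30 replicate 3, left out together after the data were seen, 4 lists were called at day 5. The medians were then 0.27 for choroid plexus (adjusted p = 0.061), 0.16 for meninges (adjusted p = 0.49) and −0.23 for immediate early genes (adjusted p = 0.28). They were 0.54 for blood (adjusted p = 0.0098) and 0.33 for oligodendrocyte genes (adjusted p = 1.6e-05). The oligodendrocyte median was −0.0052 without Fe day 5 replicate 4 (adjusted p = 0.76). The count of 11 lists became 6 without replicate 2, 5 without replicate 3 and 15 without replicate 4. With a block for slide the medians were −0.25 for immediate early genes (adjusted p = 0.042), 1.70 for choroid plexus, 1.44 for meninges and −0.01 for endothelial markers (adjusted p = 0.76). They were 0.10 for cytokines (adjusted p = 0.17), 0.09 for complement (adjusted p = 0.24) and 0.33 for the extracellular matrix (adjusted p = 0.062). The 1 array of this group that shared a slide with a control, replicate 4, differed from it by −0.11 in the immediate early score, 0.20 in meninges, −0.27 in endothelial and −0.11 in pericyte scores.

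The comparison of Fe day 15 with control is the only one in which both groups were sampled on the same day. Immediate early genes fell by 0.45 in the median, with 23 of 26 members lower, and 7 of them were called adjusted over the list alone against 0 over all genes. Markers of the dentate gyrus and of CA1 with subiculum had medians of −0.51 and −0.29 in the same comparison (adjusted p = 0.12 and 0.32). The 7 immediate early genes were Nr4a3, an orphan nuclear receptor, at −0.70 ± 0.15 (SE, n = 4 per group), Egr4, a zinc finger factor, at −0.78 ± 0.21, Btg2 at −0.58 ± 0.16, and Ier2, Npas4, Nr4a1 and Egr2. Bdnf, a growth factor of neurons that is made on activity, stood at −0.67 ± 0.11, 1.59-fold lower. Genes of the heat shock and endoplasmic reticulum stress responses rose by a median of 0.20 (16 of 22 higher), among them Herpud1 at 0.47 ± 0.15, Creld2 at 0.38 ± 0.12 and Hspa1a at 1.46 ± 0.54. Fe day 15 replicate 4 did not share this rise, with a heat shock score of −0.04 against 0.19 to 0.24 in the other 3 and Hspa1a at −0.40, below all 4 controls. Genes of neurogenesis and proliferation rose by 0.20 (13 of 17 higher), with Sox11, a factor of newborn neurons, at 0.76 ± 0.18 and the cell cycle genes Ccnb2 and Cdk1 at 0.44 ± 0.13 and 0.42 ± 0.16. This rise was largest in Fe day 15 replicate 4, with a neurogenesis score of 0.35 against 0.10 to 0.11 in the other 3.

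Camera gave immediate early genes an adjusted p of 1.8e-07, and 0.36 with an estimated correlation. The 4 Fe scores, −0.51 to −0.33, lay below the 4 control scores, −0.08 to 0.14 (exact permutation p = 0.0286, the smallest possible with 4 against 4). This p is not adjusted for the number of lists, and such a separation was not particular to this list. Dentate gyrus scores (−0.78 to −0.16 against −0.07 to 0.04) and CA1 with subiculum scores (−0.53 to −0.15 against −0.09 to 0.07) also lay below all controls. So did scores of glutamate receptors and transport, and neurogenesis and meninges scores lay above all controls. The heat shock list had an adjusted p of 0.0028, and an adjusted p of 0.98 with an estimated correlation, with 0 members called over all genes and 0 adjusted over the list alone. The neurogenesis list had an adjusted p of 0.033, an adjusted p of 0.36 with an estimated correlation, and 2 members called adjusted over the list alone. Blood markers rose by 0.72 (8 of 10, adjusted p = 0.024) and genes of glucocorticoid and circadian control by 0.22 (17 of 23, adjusted p = 0.040), both at an adjusted p of 0.98 with an estimated correlation. In the blood list S100a9 stood at 1.01 ± 0.34, Hbb, a haemoglobin chain, at 1.08 ± 0.44 and S100a8, above background on 3 of 4 Fe and 1 of 4 control arrays, at 1.62 ± 0.58. In the glucocorticoid and circadian list Tsc22d3 stood at 0.50 ± 0.19, Cry2 at −0.22 ± 0.10 and Pdk4, above background on 3 of 4 control arrays, at 1.39 ± 0.56.

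Limma called 0 of 26565 genes at day 15, with 3055 at an unadjusted p under 0.05 (1374 higher and 1681 lower) and a lowest adjusted p of 0.075. At an adjusted p under 0.1 it called 24, of which 7 were higher and 17 lower. Array weights called 184 (82 higher and 102 lower), among them Bdnf, Nr4a3, Egr4, Btg2 and Apoa1, and a fit of the 2 groups alone called 2. Without Fe day 15 replicate 4 limma called 10, and without Fe day 15 replicate 2, Fe day 5 replicate 1 or Fe day 5 replicate 4 it called 1. The genes of lowest p, none past the threshold, were Slmap, a membrane-anchored protein, at −0.55 ± 0.087 and Rrad, a small GTPase that acts on calcium channels, at 0.53 ± 0.084 (adjusted p = 0.075). Next came Bdnf, Dok3 at 0.98 ± 0.17, the survival factor Bcl2l1 at 0.42 ± 0.072 and the growth factor Egf at −0.44 ± 0.078 (adjusted p = 0.082). The count of 5 lists became 1 without control replicate 2, 3 without control replicate 4 or Fe day 15 replicate 1, 8 without Fe day 5 replicate 2 and 9 without control replicate 1. With a block for slide the medians were −0.35 for immediate early genes (adjusted p = 2.0e-05), 0.24 for heat shock genes (adjusted p = 1.9e-05) and 0.16 for neurogenesis (adjusted p = 0.021). They were 0.24 for the glucocorticoid and circadian list (adjusted p = 1.4e-04) and 0.86 for blood (adjusted p = 0.065). On slides that also held a control, the immediate early scores of replicates 1, 2 and 3 differed from that control by −0.39, −0.43 and −0.35. Fe day 15 held no array in the controls' position on the slide.

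**Figure D2:**
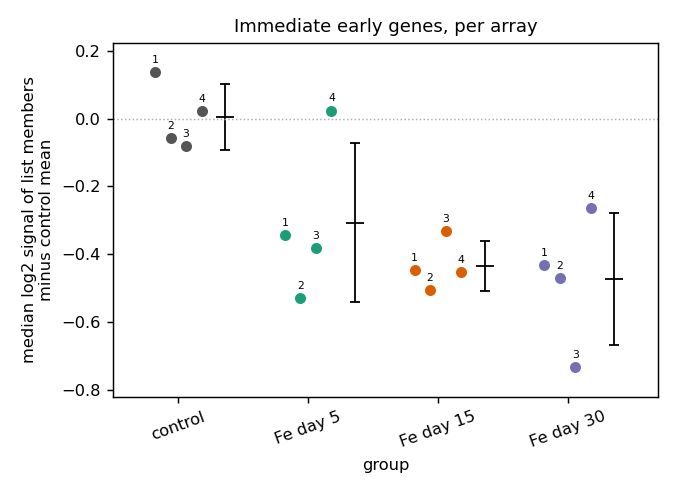
Score of the immediate early list for each array (points, numbered by replicate), in log2 units relative to the control mean, with the mean and SD of each group as a bar (n = 4). Of the 12 Fe arrays 11 lay below the lowest control, and Fe day 5 replicate 4 stood at 0.02.

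The comparison of Fe day 30 with control concerns the chronic phase. Immediate early genes fell by 0.52 in the median, with 22 of 26 members lower, and 9 were called adjusted over the list alone against 0 over all genes. They were Egr2, a zinc finger factor, at −1.51 ± 0.34 (SE, n = 4 per group, 2.85-fold lower), Egr4 at −0.86 ± 0.21, Trib1 at −1.09 ± 0.28, Arc at −1.21 ± 0.43, and Junb, Nr4a3, Nr4a1, Dusp5 and Gadd45b. Genes induced later by activity, with neuropeptides, fell by 0.19 (20 of 27 lower), among them Nptx2, a pentraxin of excitatory synapses, at −0.47 ± 0.12, Bdnf at −0.35 ± 0.11 and Rasl11b at −0.84 ± 0.28. Endothelial markers rose by 0.29 with 19 of 19 members higher, and markers of pericytes and smooth muscle by 0.45 with 12 of 13 higher. The junction protein Pecam1 stood at 1.06 ± 0.30, the efflux pump Abcg2 at 0.79 ± 0.26, and the pericyte genes Rgs5 and Pdgfrb at 0.44 ± 0.14 and 0.42 ± 0.16.

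Camera gave an adjusted p of 3.5e-08 for both immediate early genes and endothelial markers and of 5.3e-06 for pericytes, and for each of these the adjusted p was 0.45 with an estimated correlation. The list of late activity genes had an adjusted p of 0.0079, and an adjusted p of 0.57 with an estimated correlation. It held 1 member called adjusted over the list alone, and the endothelial and pericyte lists held 0, as did every list over all genes. Choroid plexus markers rose by 1.60 (17 of 17 higher, adjusted p = 2.2e-06), ependymal markers by 0.44 (11 of 11, adjusted p = 5.7e-04) and meninges markers by 0.97 (18 of 19, adjusted p = 4.6e-04). Their adjusted p was 0.64, 0.64 and 0.66 with an estimated correlation. Kcnj13, a potassium channel of choroid plexus that was above background on 2 of 4 control arrays, stood at 2.83 ± 1.6, Ace at 1.60 ± 0.83 and the ependymal gene Spef2 at 0.57 ± 0.29. Ion channel genes fell by 0.12 (26 of 34 lower, adjusted p = 0.022) and genes of glutamate receptors and transport by 0.13 (18 of 25 lower, adjusted p = 0.037), with an adjusted p of 0.66 and 0.64 with an estimated correlation. The calcium channel gene Cacna1a stood at −0.52 ± 0.20.

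Another 7 lists rose at day 30, each with 0 members called adjusted over the list alone. With an estimated correlation 0 of them were called, at an adjusted p of 0.57 for the eicosanoid list, 0.66 for blood, fatty acid oxidation and heat shock, 0.81 for cytokines and 0.85 for antigen presentation and microglia. The medians were 0.40 for blood (9 of 10 higher, adjusted p = 0.037) and 0.29 for cytokines and chemokines (21 of 24, adjusted p = 0.038). They were 0.19 for antigen presentation and interferon genes (21 of 28, adjusted p = 0.046) and 0.18 for eicosanoid genes (20 of 26, adjusted p = 0.023). The remaining lists had 0.17 for microglia and macrophages (26 of 29, adjusted p = 0.046), 0.08 for fatty acid oxidation (22 of 30, adjusted p = 0.037) and 0.08 for heat shock genes (16 of 22, adjusted p = 0.046). In Fe day 30 replicate 3 the choroid plexus score was 5.56, the meninges score 3.13 and the microglia score 1.04. Without that array the medians were −0.14 for antigen presentation (adjusted p = 0.67) and −0.014 for cytokines (adjusted p = 0.81), and with array weights antigen presentation had −0.045. Without it 3 lists were called, 2 higher and 1 lower, whereas 4 were lower with all arrays. The ion channel score of that array was −0.40, against −0.05 to −0.0033 in the other 3 of its group. Without control replicate 2 there were 8 lists. With the 3 arrays high in choroid plexus or meninges markers left out the medians were −0.35 for immediate early genes (adjusted p = 4.3e-07), 0.23 for endothelial markers (adjusted p = 3.9e-06) and 0.39 for pericytes (adjusted p = 4.3e-07). In the same setting they were 0.27 for choroid plexus (adjusted p = 0.20), 0.26 for meninges (adjusted p = 0.20), 0.04 for blood (adjusted p = 0.82) and −0.11 for microglia (adjusted p = 0.32). Immediate early genes, endothelial markers and pericytes were the 3 lists called there. Late activity genes, ion channel genes and genes of glutamate receptors and transport were not called in that setting.

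Limma called 2 of 26565 genes at day 30, both lower, with 2065 at an unadjusted p under 0.05 (828 higher and 1237 lower). Both were probes that the files do not pair with a gene, and they are given here although the rule for named genes leaves them out, having been chosen after their values were seen. Probe A_44_P226284 fell by 1.31 on the log2 scale (SE 0.16, 2.47-fold lower, adjusted p = 0.026), after −0.51 at day 5 and −0.85 at day 15. Probe A_44_P242546 fell by 0.76 (SE 0.098, 1.69-fold lower, adjusted p = 0.026), after −0.31 and −0.34. The named genes of lowest p, none past the threshold, were Bin3 at −0.38 ± 0.076, the chaperone Calr at −0.92 ± 0.19 and Cops7b at −0.42 ± 0.088 (adjusted p = 0.26). Upward they were Arhgap17 at 1.06 ± 0.23 and Ly6g6e, above background on 3 of 4 control arrays, at 2.83 ± 0.62. To these came the olfactory receptor gene Or52n4, above background on 0 of 4 control arrays and at least 2.20-fold higher (adjusted p = 0.38). The count of 2 genes became 25 with array weights (5 higher and 20 lower), 0 in a fit of the 2 groups alone and 0 with a block for slide. It was 0 without control replicate 1, 2 or 4, without Fe day 5 replicate 3, without Fe day 15 replicate 2 or 3, and without Fe day 30 replicate 1 or 4. It was 1 without Fe day 5 replicate 2, 4 without Fe day 30 replicate 3 and 9 without Fe day 5 replicate 4. With the slide block the medians were −0.32 for immediate early genes (adjusted p = 2.9e-04), 0.15 for endothelial markers (adjusted p = 0.0016), 0.27 for pericytes (adjusted p = 0.0027). They were 1.79 for choroid plexus, 0.56 for ependymal markers and 0.33 for meninges (adjusted p = 0.24), and 9 lists were called. Late activity genes had −0.13 (adjusted p = 0.069), glutamate receptors and transport −0.12 (adjusted p = 0.22), microglia 0.12 (adjusted p = 0.31), cytokines 0.17 (adjusted p = 0.35), antigen presentation 0.02 (adjusted p = 0.54) and blood 0.55 (adjusted p = 0.10) in that setting. The immediate early scores of replicates 3 and 4 differed from the control of their slide by −0.68 and −0.18, and their endothelial scores by 0.29 and 0.08. No array of this group was in the controls' position on the slide. Fe day 5 replicate 4, also outside that position, had the lowest log2 signals of its group for Bin3, Calr and Cops7b. They were −1.90 for Bin3 (−1.67 to −1.58 in replicates 1 to 3), 2.89 for Calr (3.44 to 3.89) and −2.49 for Cops7b (−2.47 to −2.27). At day 30 these signals ran from −1.85 to −1.70, 2.71 to 3.02 and −2.63 to −2.39. Position and iron cannot be told apart for these genes.

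**Figure D3:**
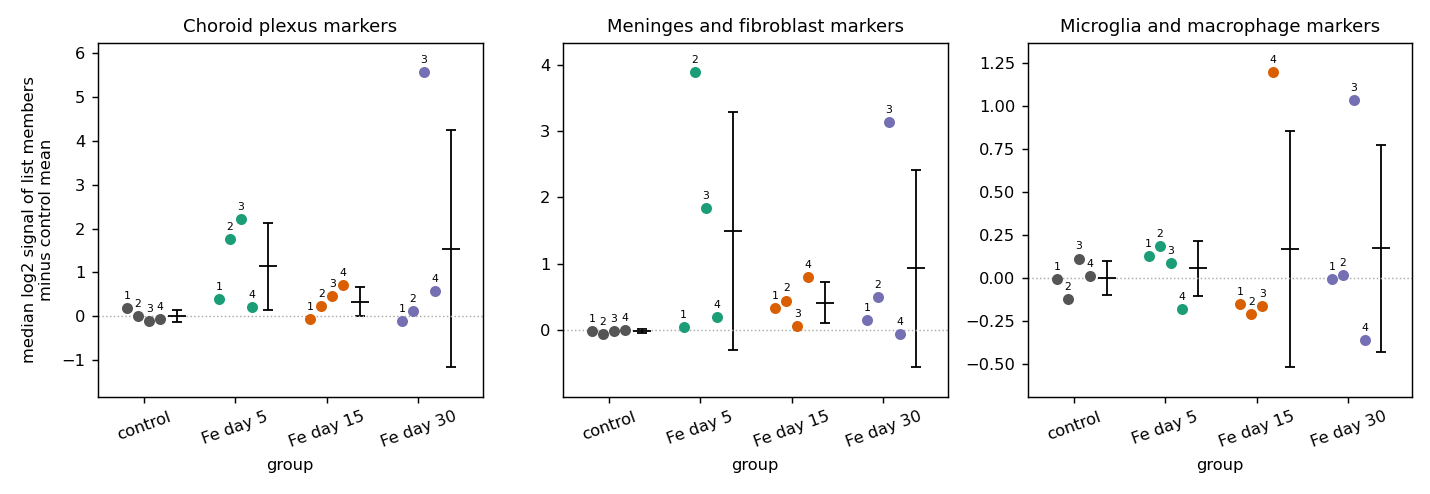
Scores of the choroid plexus, meninges and microglia lists for each array (points, numbered by replicate), in log2 units relative to the control mean, with the mean and SD of each group as a bar (n = 4). Fe day 30 replicate 3 had the highest choroid plexus score, 5.56, and Fe day 15 replicate 4 the highest microglia score, 1.20.

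The title of the series speaks of a rise of lipid metabolism genes over time, and the lists of lipid metabolism address it. For the 157 measured genes of the 6 lists together the median log2 fold change was 0.0042 at day 5, 0.0030 at day 15 and 0.0074 at day 30. Eicosanoid and phospholipase genes, which make and break down lipid signals, had medians of 0.13, 0.10 and 0.18 at days 5, 15 and 30. Hpgds, a prostaglandin D synthase, stood at 0.63 ± 0.23 (SE, n = 4 per group) at day 5, Ptgs1, a cyclooxygenase, at 0.42 ± 0.18 at day 30, and Mgll, which breaks down the endocannabinoid 2-AG, at −0.55 ± 0.21, −0.50 ± 0.21 and −0.64 ± 0.21. Pla2g2a stood at 2.12 ± 0.81 at day 5, where it was above background on 1 of 4 control arrays, and Alox15 at 1.08 ± 0.45 at day 15, with 3 of 4. Fatty acid oxidation genes, which burn fatty acids in mitochondria and peroxisomes, had medians of 0.04, 0.06 and 0.08. Acot1 stood at 0.47 ± 0.20 and Ucp2 at −0.64 ± 0.27 at day 5, and Cpt1b at 0.43 ± 0.14 at day 15. Cpt1a, the gate of fatty acid entry into mitochondria, stood at 0.27 ± 0.11 at day 30.

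Cholesterol synthesis genes had medians of −0.01, −0.04 and −0.07 (adjusted p = 0.67, 0.46 and 0.45), the day 5 test pointing up against that median. Idi1 stood at 0.25 ± 0.10 at day 5 and 0.29 ± 0.10 at day 30, and Srebf2, the factor that drives the pathway, at −0.28 ± 0.11 at day 15. Fatty acid synthesis genes had medians of −0.06, −0.08 and −0.06 (adjusted p = 0.43, 0.45 and 0.45). Acly stood at 0.22 ± 0.089, the desaturase Fads1 at −0.30 ± 0.13 and Agpat1 at −0.18 ± 0.078 at day 5. Elovl1 stood at 0.31 ± 0.12 and Gpam at −0.42 ± 0.17 at day 15. Lipid transport genes had medians of −0.04, −0.02 and 0.03 (adjusted p = 0.91, 1.00 and 0.72). Among them Apoa1, the main protein of high-density lipoprotein, stood at 1.19 ± 0.26 at day 15, where it was called adjusted over the list alone and not over all genes (adjusted p = 0.15). With array weights in limma Apoa1 was called over all genes at day 15 (adjusted p = 0.025). Apoe, the main lipid carrier of the brain, stood at −0.19 ± 0.087, −0.02 ± 0.087 and −0.05 ± 0.087, and Apod at 0.24 ± 0.21, 0.31 ± 0.21 and 0.17 ± 0.21. Sphingolipid and myelin lipid genes had medians of 0.03, −0.02 and −0.04 (adjusted p = 0.75, 0.69 and 1.00), with a mean of −0.02 and a downward test at day 5. The ganglioside enzyme gene B4galnt1 stood at −0.31 ± 0.13, −0.32 ± 0.13 and −0.31 ± 0.13, and Sphk1, which makes sphingosine 1-phosphate, at 1.13 ± 0.48 at day 5 and 0.91 ± 0.48 at day 30.

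Camera for the 157 lipid genes together gave p = 0.31, 0.91 and 0.23 at days 5, 15 and 30, and p = 0.43, 0.93 and 0.35 with an estimated correlation. Over all genes 0 of the 157 were called at each day, and 0 were called adjusted over the list alone, with 20, 14 and 6 at an unadjusted p under 0.05. Fry did not pass at any of the 3 days. The difference in score from control had a 95% interval of −3.17% to 3.88% at day 5, −4.25% to 2.72% at day 15 and −4.20% to 2.77% at day 30 (exact permutation p = 0.83, 0.71 and 0.66). The eicosanoid list rose at days 5 and 30 by camera as given above, but was not called with an estimated correlation, and had an adjusted p of 0.46 at day 15. Its score was 0.62% to 24.4% above control at day 30 in the 95% interval. This was the only interval of the lipid lists to exclude 0, and the intervals are not adjusted for the number of lists and days. The fatty acid oxidation list had an adjusted p of 0.13, 0.23 and 0.037, and of 0.75, 0.98 and 0.66 with an estimated correlation. With the 3 arrays high in choroid plexus or meninges markers left out the eicosanoid medians were 0.10 at day 5 (adjusted p = 0.45) and 0.09 at day 30 (adjusted p = 0.46), and the day 30 median of fatty acid oxidation was 0.01 (adjusted p = 0.90). With a block for slide the 157 genes had medians of −0.0057, 0.0059 and 0.0037 and did not pass camera. The eicosanoid medians with that block were 0.03 at day 5 (adjusted p = 0.11) and 0.09 at day 30 (adjusted p = 0.22), and the day 30 median of fatty acid oxidation was 0.07 (adjusted p = 0.097). In the score of the 157 genes the 6 Fe arrays on a slide with a control differed from it by −0.09 to 0.08, with 3 higher and 3 lower. Without control replicate 3 the day 30 median of the 157 genes was 0.038, and without Fe day 30 replicate 2 it was 0.020, and both passed camera at an unadjusted p under 0.05. So did, with quantile scaling, medians of 0.029 at day 5 and 0.030 at day 30, and, in the other direction, a median of −0.018 at day 5 with normexp background correction. Between Fe days the 157 genes did not pass camera in any of the 3 comparisons.

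**Figure D4:**
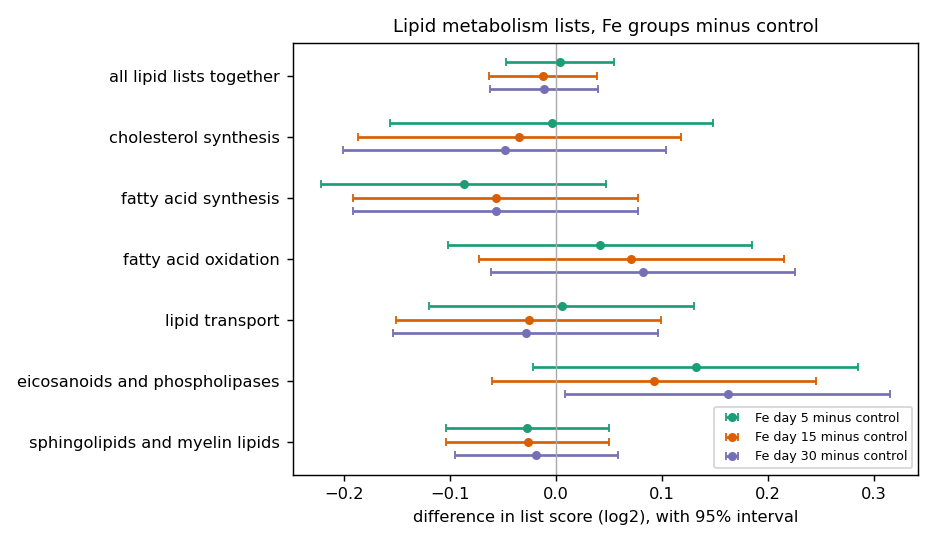
Difference in the score of each lipid list between an Fe group and control, in log2 units, with its 95% interval (n = 4 arrays per group). For the 157 lipid genes together the interval included 0 at each Fe day, and for the eicosanoid list it lay above 0 at day 30. The intervals are not adjusted for the number of lists and days.

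The comparisons between Fe days ask how the response moved with time and do not use the controls. Camera called 5, 7 and 8 lists for day 15 against 5, day 30 against 15 and day 30 against 5, and 0, 0 and 0 with an estimated correlation, where the lowest adjusted p was 0.98, 0.86 and 0.97. From day 5 to day 15, genes of glucocorticoid and circadian control rose by a median of 0.27 (adjusted p = 6.1e-06) and heat shock genes by 0.18 (adjusted p = 5.4e-04). Meninges markers fell by 1.03 (adjusted p = 3.8e-05), choroid plexus markers by 0.83 (adjusted p = 0.013) and immediate early genes by 0.13 (adjusted p = 0.041). From day 15 to day 30, endothelial markers rose by 0.30 (adjusted p = 2.3e-07), pericyte markers by 0.22 (adjusted p = 0.013), choroid plexus markers by 1.32 (adjusted p = 2.7e-04) and ependymal markers by 0.43 (adjusted p = 8.5e-04). Glucocorticoid and circadian genes fell by 0.15 (adjusted p = 6.2e-04), late activity genes by 0.20 (adjusted p = 0.041) and interneuron genes by 0.18 (adjusted p = 0.024). From day 5 to day 30, endothelial markers rose by 0.13 (adjusted p = 7.4e-04), ependymal markers by 0.39 (adjusted p = 0.0016) and heat shock genes by 0.12 (adjusted p = 0.029). Meninges markers fell by 0.59 (adjusted p = 0.023), blood markers by 0.36 (adjusted p = 0.0061), interneuron genes by 0.19 (adjusted p = 0.0046), immediate early genes by 0.12 (adjusted p = 0.0095) and oligodendrocyte genes by 0.10 (adjusted p = 0.024). Of the called lists' members 0 were called over all genes. Adjusted over the list alone there were 2 immediate early genes and 1 glucocorticoid and circadian gene from day 5 to day 15, and 3 endothelial markers and 1 pericyte marker from day 15 to day 30. The fall of immediate early genes after day 5 rested on Fe day 5 replicate 4, without which the medians were 0.06 from day 5 to day 15 and 0.0055 from day 5 to day 30, and the fall of oligodendrocyte genes became 0.05 without that array. From day 5 to day 15, without the 3 arrays high in choroid plexus or meninges markers, the meninges median was 0.33, called in the other direction (adjusted p = 0.0060), and that of choroid plexus 1.4e-05 (adjusted p = 0.83). The meninges change from day 5 to day 30 became 0.16 without Fe day 5 replicate 2, and the choroid plexus change from day 15 to day 30 became −0.20 without Fe day 30 replicate 3. With a block for slide 6 of these 20 calls were lost. The medians were 0.13 for the glucocorticoid and circadian list from day 5 to day 15 (adjusted p = 0.36) and 0.04 for pericytes from day 15 to day 30 (adjusted p = 0.46). From day 5 to day 30 they were 0.14 for ependymal markers (adjusted p = 0.47), −0.26 for blood (adjusted p = 0.064), −0.07 for immediate early genes (adjusted p = 0.064) and 0.04 for heat shock genes (adjusted p = 0.51).

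Limma called 0 genes in each comparison of Fe days, with 1913, 1724 and 787 at an unadjusted p under 0.05 for day 15 against 5, day 30 against 15 and day 30 against 5. Array weights called 2, 0 and 0, and a fit of the 2 groups alone called 0, 0 and 1. Without Fe day 15 replicate 4 limma called 13 for day 15 against 5. The genes of lowest p, none past the threshold, were Tmem202 at 0.41 ± 0.073 (SE, n = 4 per group), Slc15a4, a lysosomal histidine transporter, at 0.33 ± 0.065, and Dok3 at 0.81 ± 0.17 for day 15 against 5. Downward there they were Zfp26 at −0.59 ± 0.10, Dus2 at −0.58 ± 0.11 and Rhobtb1 at −0.52 ± 0.10. For day 30 against 15 they were Dus2 at 0.55 ± 0.11, Socs1, a brake on cytokine signalling, at 0.62 ± 0.13, Anapc1 at 0.41 ± 0.084, Slc15a4 at −0.35 ± 0.065, Cadm4 at −0.37 ± 0.085 and Dpysl5 at −0.63 ± 0.14. For day 30 against 5 they were Ly6g6e at 2.56 ± 0.62, Tmem202 at 0.30 ± 0.073, Lsm6 at 1.16 ± 0.33, Rdh13 at −0.46 ± 0.12, Myo9a at −0.24 ± 0.064 and P3h4 at −0.27 ± 0.074. The F-test over the 4 groups called 0 genes, with 2215 at an unadjusted p under 0.05 and a lowest adjusted p of 0.15. It called 17 with array weights and 2 without Fe day 5 replicate 4 or without Fe day 15 replicate 4.

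The fold changes of the 3 Fe days against the same 4 controls correlated across genes, which are not independent replicates, at 0.67 for days 5 and 15, 0.75 for days 5 and 30 and 0.64 for days 15 and 30. Groups simulated without any change against shared controls gave 0.50. That simulation gave every group the same spread. The controls varied less than the Fe groups (median SD of 0.13, against 0.18 to 0.19), so 0.50 is not an exact reference here. With the 4 controls divided so that each day had its own pair, the correlations averaged 0.43, 0.50 and 0.38 over 6 divisions. Calls shared between days numbered 0, in the data and in the simulation. With 0 genes called at day 5 and 0 at day 15 no other count was possible, so this says nothing about overlap.

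Markers of glia, injury and seizure named in advance did not pass at any day. Gfap, the intermediate filament of astrocytes, stood at −0.12 ± 0.31, 0.09 ± 0.31 and 0.44 ± 0.31 (SE, n = 4 per group) at days 5, 15 and 30, and Vim at 0.83 ± 0.65, 0.68 ± 0.65 and 0.67 ± 0.65. The microglial genes Aif1 and Cd68 stood at 0.21 ± 0.27, 0.04 ± 0.27 and 0.15 ± 0.27 and at 0.30 ± 0.86, 0.63 ± 0.86 and 0.64 ± 0.86. Hmox1, which breaks down haem and releases iron, stood at −0.08 ± 0.21, 0.38 ± 0.21 and 0.11 ± 0.21, and Ptgs2, above background on 3 of 4 control arrays, at −0.43 ± 0.37, −0.17 ± 0.37 and −0.07 ± 0.37. Npy, a peptide of interneurons, stood at −0.16 ± 0.26, −0.25 ± 0.26 and −0.42 ± 0.26, Fos at −0.20 ± 0.32, −0.48 ± 0.32 and −0.52 ± 0.32, and Ttr, the main secreted protein of the choroid plexus, at 2.72 ± 1.8, 1.02 ± 1.8 and 2.69 ± 1.8. Arc and Bdnf, which have no call over all genes either, except Bdnf at day 15 with array weights, stood at −0.85 ± 0.43 at day 15 and at −0.31 ± 0.11 at day 5.

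Gene lists that camera did not call at any Fe day against control are given with their medians at days 5, 15 and 30. They held 0 genes called over all genes, and adjusted over the list alone 1, in iron handling at day 5. Genes of the oxidative stress response, which detoxify oxygen radicals, had 0.03, 0.06 and 0.05 (lowest adjusted p = 0.18) and genes of iron handling 0.03, 0.06 and 0.10 (lowest adjusted p = 0.15). Astrocyte markers had −0.03, 0.01 and −0.04 (lowest adjusted p = 0.34) and genes of reactive astrocytes 0.15, 0.10 and 0.27 (lowest adjusted p = 0.074). Lymphocyte genes had 0.22, 0.01 and 0.17 (lowest adjusted p = 0.22) and oligodendrocyte precursor genes 0.05, −0.09 and −0.03 (lowest adjusted p = 0.56). Markers of the dentate gyrus had −0.49, −0.51 and −0.13 (lowest adjusted p = 0.12) and markers of CA1 with subiculum −0.34, −0.29 and −0.31 (lowest adjusted p = 0.096). Markers of CA3 with CA2 had −0.09, 0.01 and 0.05 (lowest adjusted p = 0.75) and markers of regions outside the hippocampus 0.07, −0.0042 and −0.09 (lowest adjusted p = 0.68). Interneuron genes had 0.11, 0.08 and −0.02 (lowest adjusted p = 0.056) and general neuronal genes −0.04, −0.06 and −0.08 (lowest adjusted p = 0.085). Genes of GABA receptors and transport had 0.02, −0.0022 and −0.06 (lowest adjusted p = 0.74) and genes of mitochondrial respiration 0.01, 0.01 and −0.01 (lowest adjusted p = 0.67).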

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

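The tests of array position, slide, fewer neurons, dilution, age, other tissue and blood were chosen after the results were seen, and the counts over other splits of the arrays were chosen before.

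Single arrays stood far from the others of their group in 20 of the 152 groups of 4 values examined, where chance flags about 1 in 20 groups, here 7.6. Fe day 15 replicate 4 stood apart with scores of 1.20 for microglia, 1.02 for complement, 0.60 for the extracellular matrix, 0.35 for neurogenesis and −0.041 for heat shock genes, and with log2 values relative to control of 1.99 for Vim, 0.87 for Aif1 and 3.47 for Cd68. Fe day 30 replicate 3 stood apart with scores of 5.56 for choroid plexus, 1.28 for antigen presentation, 0.94 for the extracellular matrix and −0.40 for ion channels, and with 2.33 for Vim, 0.95 for Aif1 and 3.15 for Cd68. Fe day 5 replicate 2 stood apart with scores of 1.12 for the extracellular matrix and −0.32 for glutamate receptors and transport. Control replicate 2 had a blood score of −0.26. The number of spots above background was low in control replicate 4, at 32189, and in Fe day 30 replicate 1, at 32829.

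Camera with the preset correlation called 20 differences between Fe days, each a test of the difference itself. From day 5 to day 15 the medians were −0.83 for choroid plexus, −1.03 for meninges, −0.13 for immediate early genes, 0.27 for glucocorticoid and circadian genes and 0.18 for heat shock genes. From day 15 to day 30 they were 0.30 for endothelial, 0.22 for pericyte, 1.32 for choroid plexus and 0.43 for ependymal markers, −0.18 for interneuron, −0.20 for late activity and −0.15 for glucocorticoid and circadian genes. From day 5 to day 30 they were −0.10 for oligodendrocyte genes, 0.13 for endothelial, 0.39 for ependymal, −0.59 for meninges and −0.36 for blood markers, −0.19 for interneuron genes, −0.12 for immediate early genes and 0.12 for heat shock genes. With an estimated correlation 0 of the 20 were called.

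Immediate early genes were lower in 11 of 12 Fe arrays than in any control. Their mean scores at days 5, 15 and 30 were −0.31, −0.43 and −0.47, against −0.07, −0.08 and −0.10 for general neuronal genes. This argues against fewer neurons of all kinds, or dilution by other cells, as the whole cause. The gap between both lists was wider than in any control in 11 of the 12. That count was chosen with the scores known, and the controls spanned a narrow range, so it adds no independent test. Fewer dentate granule or CA1 neurons stay a candidate explanation, because medians at days 5, 15 and 30 were −0.49, −0.51 and −0.13 for dentate gyrus and −0.34, −0.29 and −0.31 for CA1 with subiculum markers, beside −0.28, −0.45 and −0.52, and immediate early genes lay further below the lower of both lists than in any control in 2 of 12 Fe arrays. Slide alone is argued against by 6 of 6 Fe arrays below the control of their slide. These pairs used 4 controls, all in position 1 and the Fe arrays in other positions, so position could give the same. At day 5 the only such pair held replicate 4 (−0.11), whose score of 0.02 lay within the control range. Among arrays in position 1 Fe day 5 lay below control by −0.42, which argues against position alone at day 5 (exact permutation p = 0.0286). That p is the smallest possible for 3 against 4. Those 3 Fe arrays lay on slides without a control, so slide could give that difference. They leave out replicate 4, the Fe day 5 array without a fall. They also include replicates 2 and 3, which were high in choroid plexus and meninges markers, so the difference rests in part on those arrays. For days 15 and 30 position and group cannot be told apart, because no array of these groups was in the controls' position, and the day 15 median with position as a block, −0.78, rests on Fe day 5 replicate 4 alone as the link and decides nothing. Age is argued against at day 15, where 4 of 4 Fe arrays lay below every control, operated on at the same age and sampled on the same day, and stays open at days 5 and 30, as do, untested, the hour of killing, handling and a response to the seizures or the iron.

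Choroid plexus and meninges markers were high in Fe day 5 replicates 2 and 3 and Fe day 30 replicate 3. At least 82.4% of choroid plexus markers in each of these arrays lay above the highest control, but the arrays were picked for such scores, so tissue of the choroid plexus and meninges in the dissected sample and a response cannot be told apart by this share. Ttr, the choroid plexus's main secreted protein, stood above its control mean by 5.98 on the log2 scale in Fe day 5 replicate 3 and 9.16 in Fe day 30 replicate 3 but by 1.76 in Fe day 5 replicate 2, near the highest control at 1.42, which leaves open how much choroid plexus that array held. Of the choroid plexus markers 14 of 17 were above background on all control arrays and 1 is also in the meninges list, of whose 19 members 17 were above background on all controls. A response shared by the Fe animals stays open, because 11 of 12 Fe arrays had a meninges score above the highest control. That control score was only 0.0059, so that a score as low as 0.046, in Fe day 5, was counted.

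Microglia markers were high in Fe day 15 replicate 4 and Fe day 30 replicate 3, at 1.20 and 1.04, and at most 0.19 in the other Fe arrays. Blood in the sample is argued against by 4 other Fe arrays with blood scores of 0.86 to 1.77 and microglia scores of at most 0.19. Tissue of the choroid plexus and meninges is argued against for Fe day 15 replicate 4 by 2 other arrays with more meninges signal and microglia scores of at most 0.19. For Fe day 30 replicate 3, whose choroid plexus score of 5.56 was far above the next highest of 2.21, such tissue and a response of microglia cannot be told apart. A microglial response may therefore remain in Fe day 15 replicate 4, as a hypothesis from 1 array.

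The counts were set against the 35 splits of the 8 arrays of each comparison into 4 and 4, the real split included. For day 30 only 1 split, the real one, gave as many as 2 genes, with at most 1 in the others. This is the smallest share that 35 splits can give. It rests on 2 genes against 1, among several comparisons tested this way, so chance is not excluded. The real split also separates the controls' position from the others. The day 30 count was 0 with a slide block (lowest adjusted p = 0.22), in a fit of the 2 groups alone (lowest adjusted p = 0.087) and without control replicate 1, 2 or 4, Fe day 5 replicate 3, Fe day 15 replicate 2 or 3, or Fe day 30 replicate 1 or 4. Every split is as large as a real count of 0, so the other counts say nothing about chance: 35 splits at day 5, with at most 0 elsewhere, 35 at day 15, with up to 85, and 100 of 100 drawn for the F-test, with up to 265. The same holds for the Fe days against each other, with 35 splits each and the highest others at 217, 47 and 2 for day 15 against 5, day 30 against 15 and day 30 against 5. Of genes at an unadjusted p under 0.05 the real split had the most of the 35 at day 5 (2746, against at most 2451), at day 15 (3055, against 2094) and at day 30 (2065, against 1924). Between Fe days 9, 14 and 27 splits had as many as the real 1913, 1724 and 787, and in the F-test 7 of 100 had as many as 2215.

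For the lists, 16 splits gave as many as the real 11 at day 5 (highest other 23), 30 as many as 5 at day 15 (14) and 21 as many as 16 at day 30 (25), so chance cannot be excluded for these counts. Between Fe days 33 splits gave as many as 5 for day 15 against 5 (highest other 22), 27 as many as 7 for day 30 against 15 (23) and 25 as many as 8 for day 30 against 5 (26), so chance cannot be excluded there either. For the 157 lipid genes 23, 34 and 22 splits gave a camera p as small as the real p of 0.31, 0.91 and 0.23 at days 5, 15 and 30. The lowest of the other splits were 4.0e-04, 7.2e-05 and 8.7e-07, and chance cannot be excluded.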

How the results depend on the processing

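Values with arrays high in other markers left out, with a position block, with marked spots kept, with the 12 Fe arrays pooled and of permuted scores were chosen after seeing the data. For the named genes, of whose 189 results 0 were called, 6217 values from 33 settings held 23 past the threshold of their setting. Of these 23, 6 passed only because that setting raised the threshold to an adjusted p of 0.1, and 13 came from array weights. Another 71 values changed sign without a call. Of the 2278 values for the called lists and the lipid lists 350 lost their call, 5 gained one and 31 reversed, and 47 changed sign without a call, and of 102 for the lipid genes 97 kept their side of the threshold. Where counts of genes changed, the cause was not tested, except that leaving out arrays leaves fewer of them. The share of spots above background, 74.2% to 81.6% per array, limits what dim genes can show. Scan date was not run. Replicate numbers showed no pairing on average (mean r = −0.0030 over 24 same-number pairs, −0.41 to 0.39). Of the 16 arrays, 8 correlated best with an array of the same number in another group, so some pairing is not excluded.

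With normexp 17 lists were called at day 5 and 8 at day 15, and the lipid median at day 5 was −0.018, past the threshold in the other direction. Quantile scaling gave lipid medians of 0.029 at day 5 and 0.030 at day 30, both past the threshold, 8 genes at day 30 and 1 in the F-test. Median centring gave 9 genes at day 30 and 1 in the F-test. Without the filter on dim probes 1 gene was called at day 5, 1 at day 15, 1 in both and 1 in the F-test. Every probe on its own gave 18 lists at day 5 and 9 at day 15. A fit of the 2 groups alone gave 2 genes and 11 lists at day 15, 0 genes at day 30 and 1 for day 30 against 5. A replicate block gave 1 gene at day 15 and 1 shared between days. A slide block gave 0 genes and 9 lists at day 30, and −0.011 for endothelial markers at day 5. Array weights gave 184 genes at day 15, 25 at day 30, 2 for day 15 against 5, 10 shared and 17 in the F-test, 7 lists at day 5 and 4 at day 30, and −0.045 for antigen presentation at day 30. With an absolute log2 fold change of at least 1 there was 1 gene at day 30. At an adjusted p under 0.1 there were 24 genes at day 15, 7 at day 30 and 2 shared. With an estimated correlation, and with fry, 0 lists were called at days 5, 15 and 30 and 0 between days, the lowest adjusted p being 0.67, 0.36 and 0.45, and 0.39, 0.063 and 0.12.

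Without the 3 arrays high in choroid plexus or meninges markers there were 4, 11 and 3 lists at days 5, 15 and 30, 1 gene at day 15 and 0 at day 30. Endothelial markers were then −0.0055 at day 5, and at day 30 microglia −0.11, cytokines −0.014 and antigen presentation −0.14. Choroid plexus was 1.4e-05 and meninges 0.33 (adjusted p = 0.0060) for day 15 against 5, choroid plexus −0.20 for day 30 against 15 and meninges 0.059 for day 30 against 5. Without these and Fe day 15 replicate 4 there were 5, 10 and 4 lists, 8 genes at day 15, 0 at day 30, 1 for day 15 against 5 and 1 in the F-test. Endothelial markers were −0.0055 at day 5, and at day 30 microglia −0.11 (adjusted p = 0.022), cytokines −0.014 and antigen presentation −0.14, with meninges at 0.16 for day 15 against 5 and 0.059 for day 30 against 5. A position block says nothing reliable here, because 1 array, Fe day 5 replicate 4, is its only link between the controls' position and the others. Day 5 against control is then the same difference as without that array, and day 30 against 15 rests on Fe day 30 replicates 1 and 2. It gave 15 genes and 16 lists at day 15, 17 genes at day 30, 22 for day 15 against 5, 10 for day 30 against 15, 26 for day 30 against 5, 9 shared and 21 in the F-test. Oligodendrocyte genes were then −0.0052 at day 5, choroid plexus 0.22 and meninges 0.31 for day 15 against 5, choroid plexus −0.29 for day 30 against 15, and meninges 0.16 and heat shock genes −0.021 for day 30 against 5.

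Leaving out 1 array at a time, genes called ranged from 0 to 0 at day 5 and 0 to 10 at day 15 (10 without Fe day 15 replicate 4, 1 without Fe day 5 replicate 1 or 4 or Fe day 15 replicate 2). They ranged from 0 to 9 at day 30 (9 without Fe day 5 replicate 4, 4 without Fe day 30 replicate 3, 1 without Fe day 5 replicate 2, and 0 without control replicate 1, 2 or 4, Fe day 5 replicate 3, Fe day 15 replicate 2 or 3, or Fe day 30 replicate 1 or 4). They ranged from 0 to 13 for day 15 against 5 (13 without Fe day 15 replicate 4), 0 to 0 for day 30 against 15, 0 to 0 for day 30 against 5, and 0 to 2 in the F-test (2 without Fe day 5 replicate 4 or Fe day 15 replicate 4). Shared calls were 0 to 1 (1 without Fe day 5 replicate 1 or 4). Lists ranged from 5 (without Fe day 5 replicate 3) to 15 (without Fe day 5 replicate 4) at day 5, with 6 without Fe day 5 replicate 2. They ranged from 1 (without control replicate 2) to 9 (without control replicate 1) at day 15, with 3 without control replicate 4 or Fe day 15 replicate 1 and 8 without Fe day 5 replicate 2. At day 30 they ranged from 3 (without Fe day 30 replicate 3) to 20, with 8 without control replicate 2, and between Fe days from 17 to 29. Lipid medians ranged from −0.0087 to 0.035, −0.016 to 0.031 and −0.013 to 0.038 at days 5, 15 and 30, passing at 0.038 without control replicate 3 and 0.020 without Fe day 30 replicate 2. Reversed were meninges for day 30 against 5, at 0.16 without Fe day 5 replicate 2, and without Fe day 5 replicate 4 oligodendrocyte genes at day 5 (−0.0052) and for day 30 against 5 (0.046) and immediate early genes for day 15 against 5 (0.056) and day 30 against 5 (0.0055). Without Fe day 30 replicate 3 microglia (−0.11), cytokines (−0.014) and antigen presentation (−0.14) at day 30 and choroid plexus for day 30 against 15 (−0.20) reversed. The lists with reversals ranged from −0.0052 to 0.28 for oligodendrocyte genes at day 5, and at day 30 from −0.11 to 0.33 for microglia, −0.014 to 0.43 for cytokines and −0.14 to 0.30 for antigen presentation. For day 15 against 5 immediate early genes ranged from −0.23 to 0.056, and for day 30 against 15 choroid plexus from −0.20 to 1.91. For day 30 against 5 the ranges were −0.26 to 0.046 for oligodendrocyte genes, −1.43 to 0.16 for meninges and −0.22 to 0.0055 for immediate early genes. For the reversed lists the cause was not tested.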

Other observations

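The pooled comparison and the counts of arrays beyond the controls were chosen after the results by day were seen, and no explanation was tested for them.

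With the 12 Fe arrays pooled against the 4 controls, some neuronal lists lay low in most arrays and others did not, and no test covered them together. The controls spanned a narrow range, and in some lists Fe arrays lay beyond it on both sides. Genes of iron handling had 8 of 12 above and 3 below, and markers of regions outside the hippocampus 4 above and 6 below. Such counts are therefore no test of a shift. Immediate early genes had a median log2 fold change of −0.40 (adjusted p = 3.6e-07, and an adjusted p of 0.54 with an estimated correlation). Genes of glutamate receptors and transport had a score below the lowest control in 11 of 12 Fe arrays, and markers of the dentate gyrus and of CA1 with subiculum in 10 of 12 each (adjusted p = 0.088 for both, not called at 0.05). Markers of CA3 with CA2 lay below the lowest control in 2 of 12 and above the highest in 1, interneuron genes below in 2 and above in 5, and genes of GABA receptors and transport below in 5 and above in 2, with medians of −0.05, 0.04 and −0.0031. General neuronal genes lay below the lowest control in 7 of 12 and ion channel and late activity genes in 9 of 12 each, with 0 above the highest in each list. Genes of neurogenesis and proliferation lay above the highest control in 10 of 12, meninges markers in 11, choroid plexus markers in 9 and pericyte markers in 8. On slides that also held a control, glutamate receptor and transport genes were lower than that control in 6 of 6 Fe arrays (−0.29 to −0.06), dentate gyrus markers lower in 6 of 6 (−0.49 to −0.12), and markers of CA1 with subiculum lower in 4 and higher in 2 (−0.91 to 0.14). Glucocorticoid and circadian genes were higher there in 6 of 6 (0.04 to 0.29), but over all 12 Fe arrays 5 lay above the highest control and 5 below the lowest (adjusted p = 0.89). In this pooled comparison limma called 0 genes, with 3468 at an unadjusted p under 0.05 and a lowest adjusted p of 0.13, and camera called 17 lists, with 0 called by an estimated correlation, where the lowest adjusted p was 0.54.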
